A study of Mus musculus with 2 samples.

How the data were processed

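The series holds single-cell RNA libraries from the aortas of Ldlr-deficient mice, 1 library per group. Per the labels, mice entered at 8 weeks of age, ate a western diet for 3 months and then chow for 1 month. During the chow month they received 5 weekly intravenous injections at 1 mg/kg, in saline with 5% DMSO, of either anti-miR-33pHLIP or ScrpHLIP. A pH low-insertion peptide (pHLIP) is a carrier that crosses cell membranes in acidic tissue. The construct named anti-miR-33pHLIP carries an inhibitor of the microRNA miR-33, and ScrpHLIP carries a scrambled control. The adventitia was stripped after 7 min of collagenase, the tissue was digested for 40 min with collagenase and elastase, and live single cells were sorted without a lineage gate. The number of animals behind each library is not stated.

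The deposited matrices hold counts: whole-number UMIs (unique molecular identifiers, 1 per captured RNA molecule) per gene and cell barcode, made by the authors with 10x 3′ chemistry (version 3). Per the file headers the matrix software had version 3.1.0. The submitters' processing notes name Cell Ranger, R 3.0, Seurat 3 and the mouse build mm9. The feature list has 31053 genes with Ensembl identifiers, and 36 symbols occur more than once. Classes were rebuilt here from the counts, and a difference from the study's own may come from that. The ScrpHLIP library had 7771 barcodes and 64072173 UMIs, and the anti-miR-33pHLIP library had 13424 barcodes and 78887008 UMIs. No barcode had fewer than 500 UMIs. Median UMIs per barcode were 6262 in ScrpHLIP and 4590 in anti-miR-33pHLIP, and median detected genes were 2072 and 1722.

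Filters, classes, markers, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Cells needed at least 300 detected genes and at most 10% mitochondrial UMIs, which 6508 ScrpHLIP and 11357 anti-miR-33pHLIP barcodes met. Doublets were scored per library with Scrublet as built into scanpy 1.11.5, and the top share expected from loading, 0.8% per 1000 barcodes, was removed (483 and 1442 barcodes by score, of which 405 and 1265 had passed the filter). Scrublet's automatic threshold marked only 2 barcodes (0.0257%) in ScrpHLIP, so it did not work there, and 323 (2.41%) in anti-miR-33pHLIP. This left 6103 and 10092 cells. Both libraries were clustered together without integration, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9, anndata 0.12.19, Python 3.11.15).

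Clusters were named only from the fixed markers, so every class name below means "-like". A name needed at least 3 detected markers, meaning at least 10% of the cluster's cells and 2-fold above the other clusters, and a marker among the cluster's top 10 genes or a clear lead over the next type. A cluster with a median UMI count under 1/3 of its library's and no marker of the name among its top 10 genes stayed unnamed. The lead rule (1 log2 unit) and a set of immature thymocyte markers were added after seeing the data. They left unnamed a stromal cluster led by Crlf1, Fbln2 and Vcam1 and a cluster led by Trbc1, Dntt and Rag1. A cluster led by cell cycle genes was split again before naming. Macrophage-like cells were clustered again and given states from fixed state markers. Because those markers are compared too, the state shares given first come from a clustering that left out the state markers and the interferon list, an alternative chosen after seeing the data.

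With 1 library per group no test between groups is possible, and there is no replicate check. UMIs were summed over the cells of a class, and CPM (counts scaled to a class total of 1e6) were compared as the ratio of anti-miR-33pHLIP to ScrpHLIP. CPM have exact Poisson 95% intervals, ratios exact conditional binomial 95% intervals and shares of cells exact Clopper-Pearson 95% intervals. All of these intervals cover counting error only, not differences between animals or preparations. Genes at 0 UMIs in a library are compared with a floor of 3 UMIs. Classes with at least 50 cells in each library were compared. Named genes had at least 50 UMIs in the higher library and at least 25% of the highest class's CPM there, with the same direction under TMM scaling and with the mean of per-cell CPM. They were ranked by the interval bound nearest to 1: 12 each way in macrophage-like cells and 6 each way in every other class, plus 7 genes fixed in advance. Mitochondrial, ribosomal, hemoglobin, antigen receptor and unnamed genes were left out of that ranking, as were Xist, Tsix and the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y. Other X-linked genes were kept.

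For 24 fixed gene lists, the median log2 ratio was taken over members with at least 20 UMIs in both libraries together, with a prior of 0.5 UMIs, and only where at least 5 members qualified. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, is a description of these 2 libraries, not a test. A member counts as higher or lower from 1.25-fold, called the threshold. The lists cover published miR-33 targets, cholesterol efflux and LXR targets, cholesterol biosynthesis, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, extracellular matrix, matrix proteases, protease inhibitors, NF-kB inflammatory genes, alternative activation, lipid-associated macrophages, resident macrophages, interferon response, MHC class II presentation, efferocytosis and complement, autophagy and lysosome, chemotaxis and retention, cell cycle, contractile smooth muscle, modulated smooth muscle, endothelial activation, T cell regulation, and dissociation stress. Seed sites are matches to positions 2 to 8 of miR-33 in annotated 3′ UTRs, taken by Ensembl identifier from GENCODE M21, which is not the noted build; no coordinates are used. The cycling share counts cells with a UMI of Mki67 or Top2a after thinning every cell to 2000 UMIs.

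Simulated macrophage counts were drawn from the Poisson model that the intervals assume, each gene independently. Spread between cells and genes that vary together were not simulated, so the rates below check the code and not the intervals on these data. With no difference, 95.4% of 11142 intervals held the true ratio. Of 50 genes each, 40% were placed beyond 1 in the right direction at a true 1.25-fold difference, 72% at 1.5-fold and 90% at 2-fold. Unchanged lists fell outside the middle 95% of random lists in 4.5% of 200 draws. Alternatives covered the cell filter (none, or at least 1000 genes and at most 5% mitochondrial UMIs), doublets kept or removed automatically, Leiden resolution 0.5 and 2, each library clustered alone, edgeR 4.0.16 TMM and DESeq2 1.42.0 size factors in R 4.3.3, the mean of per-cell CPM, count minimum, prior count, site length, thinning and the denominator.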

Results

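Aortic cells from Ldlr-deficient mice given anti-miR-33pHLIP during 1 month of chow were compared with cells from mice given the scrambled ScrpHLIP, with 1 library per group. Macrophage-like and T cell-like cells made up a larger share of the anti-miR-33pHLIP library, and cartilage-like modulated smooth muscle cells and endothelial cells a smaller share. Within macrophage-like cells, interferon-response and MHC class II genes were higher and NF-kB, cholesterol biosynthesis and cell cycle genes were lower. The published miR-33 target Abca1, which exports cholesterol, was 1.10 times as high (95% interval 1.05–1.16), or 1.03 (0.986–1.08) with doublets kept, and the miR-33 target list as a whole sat at a median log2 ratio of 0.01. As class values, interferon genes were also higher in smooth muscle and endothelial cells and lower in fibroblast-like cells. Inside contractile smooth muscle clusters 11 and 14 they lay within the range of random lists.

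Macrophage-like cells, the lipid-clearing phagocytes of plaque, were 12.6% of ScrpHLIP cells (767, 95% interval 11.8–13.4%) and 17.8% of anti-miR-33pHLIP cells (1800, 17.1–18.6%), a ratio of 1.42 (1.30–1.55), and from 1.15 at the automatic doublet threshold to 1.69 with each library clustered alone. The T cell share was 2.65% (162 cells, 2.27–3.09%) and 6.16% (622, 5.70–6.65%), 2.32 times as high (1.95–2.78), and 1.46 (1.21–1.77) with the strict cell filter. Monocyte-like cells, the blood precursors of plaque macrophages, were 1.00% (61 cells) and 1.48% (149), 1.48 times as high (1.09–2.02), a direction that did not hold: the ratio was 0.454 (0.355–0.578) with each library clustered alone and 1.00 among leukocytes. Conventional dendritic cells, which prime T cells, were 2.42% (148) and 2.29% (231), a ratio of 0.944 (0.765–1.17), and neutrophils 0.803% (49) and 0.743% (75), 0.926 (0.637–1.36). B cells were rare, 7 and 28 cells (0.115% and 0.277%). Cells were sorted for viability alone, so shares follow digestion and sorting as well as the tissue, and depth differed between libraries (median 8180 and 5468.5 UMIs per kept cell).

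The class named modulated smooth muscle cells, a name for cells that have left the contractile state, here carried cartilage genes. It was 40.8% of ScrpHLIP cells (2493, 39.6–42.1%) and 32.5% of anti-miR-33pHLIP cells (3278, 31.6–33.4%), a ratio of 0.795 (0.755–0.838). Smooth muscle markers were at 351 and 453 CPM in this class, against 25202 and 22646 CPM in contractile smooth muscle cells. Whether its cells came from smooth muscle or from another source was not tested. Contractile smooth muscle cells were 11.2% (683) and 11.9% (1197), 1.06 times as high (0.964–1.17), but 0.875 (0.789–0.971) at resolution 2 and 1.30 (1.14–1.49) with the strict cell filter, and in ScrpHLIP the largest part was a cluster with few UMIs (275 cells, against 238), while in anti-miR-33pHLIP it was cluster 11 (431, against 138). Endothelial cells were 7.54% (460, 6.89–8.23%) and 4.72% (476, 4.31–5.15%), 0.626 times as high (0.549–0.713). Within that class, cluster 22 held 76 cells (1.245%) of ScrpHLIP and 7 (0.0694%) of anti-miR-33pHLIP, and a cluster from nearly 1 library may be that library and not a cell type. Fibroblast-like cells were 1.46% (89) and 1.92% (194), 1.32 times as high (1.02–1.71), but 0.968 with the strict cell filter.

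Unnamed cells were 19.4% of ScrpHLIP (1184) and 20.2% of anti-miR-33pHLIP (2042). The largest unnamed cluster was stromal and led by Crlf1, Fbln2 and Vcam1, with 7.46% (455) and 9.71% (980), 1.30 times as high. It was kept out of the stromal classes by the naming lead set after seeing the data, as was a small cycling stromal group (0.295% and 0.357%). A cluster of macrophage markers with few UMIs held 6.10% (372) and 3.92% (396), and a cluster led by nuclear RNA held 4.26% (260) and 2.99% (302). Among leukocytes only (1194 and 2905 cells), macrophages were 64.2% and 62.0%, a ratio of 0.965 (0.886–1.05), since the T cell share was larger still. T cells stayed higher on that base, 13.6% and 21.4% (1.58, 1.33–1.89), and dendritic cells were lower, 12.4% and 7.95% (0.642, 0.520–0.794), although with each library clustered alone their share of all cells was 1.645 times as high (1.27–2.14).

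**Figure D1:**
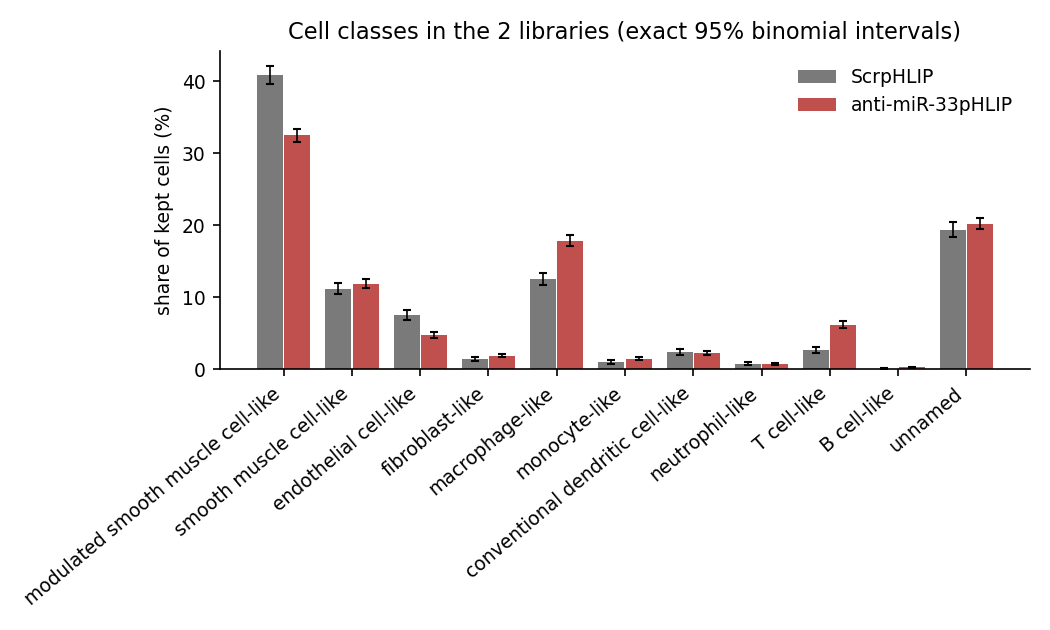
Shares of kept cells per class in each library with intervals for counting error. Macrophages were 12.6% and 17.8%, T cells 2.65% and 6.16%, modulated smooth muscle cells 40.8% and 32.5%.

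An interferon-response state of macrophages held 1.96% of ScrpHLIP macrophages (15 cells, 1.10–3.21%) and 14.6% of anti-miR-33pHLIP macrophages (263, 13.01–16.3%), 7.47 times as high (4.45–13.5). An unnamed group led by Vcam1, Ifit1 and Ifih1 (57 and 191 cells) also carries interferon genes, and with it the shares were 9.39% (72) and 25.2% (454), 2.69 times as high (2.09–3.50). The inflammatory state, with its cytokine and chemokine genes, held 17.1% (131) and 11.1% (199), 0.647 times as high (0.517–0.813), but 0.905 at resolution 0.5 and 1.12 with the few-UMI macrophage cluster added. Trem2 foamy cells, which store lipid, were 25.2% (193) and 23.2% (418), 0.923 times as high (0.776–1.10), but 1.22 (0.990–1.51) with the few-UMI macrophage cluster added. Resident-like macrophages were 1.56% (12) and 2.11% (38), 1.35 (0.690–2.84). Cells of a cycling state were 4.56% (35) and 3.33% (60), 0.730 (0.474–1.14). The other 49.7% and 45.7% of macrophages had none of these states. They include a group led by dissociation-stress genes (100 and 177 cells) and a group led by cartilage genes (23 and 35). With the state genes kept in the clustering, the interferon state was 1.83% (14) and 15.8% (285), a ratio of 8.67 (5.09–16.1), but 2.82 (1.96–4.17) at resolution 2 and 3.90 with cells as deposited, and the inflammatory state 20.1% and 14.6%, 0.725. Most macrophages fell into 2 clusters: foamy cluster 7 was the larger in ScrpHLIP (415, with 316 in chemokine-rich cluster 20), and cluster 20 in anti-miR-33pHLIP (884, with 856 in cluster 7).

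**Figure D2:**
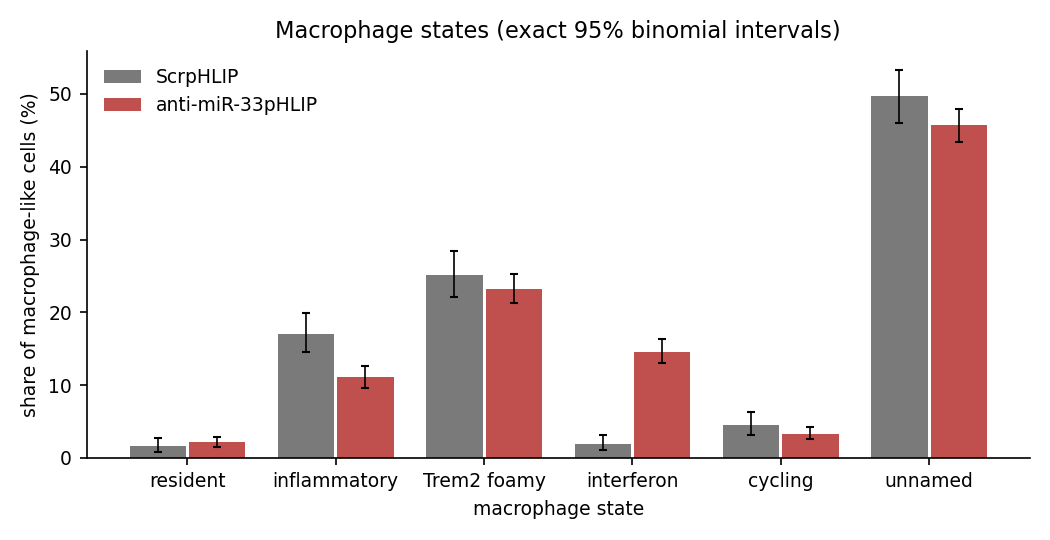
Macrophage states from the clustering without state markers and interferon genes. The interferon state was 1.96% and 14.6% of macrophages, the inflammatory state 17.1% and 11.1%.

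Genes higher in anti-miR-33pHLIP macrophages were led by interferon targets and chemokines that draw leukocytes. Cxcl9 (ENSMUSG00000029417), a chemokine for activated T cells, had 9 UMIs in 5 cells in ScrpHLIP and 394 in 61 cells in anti-miR-33pHLIP, 1.30 and 36.1 CPM, 27.7 times as high (14.5–61.1). Ccl8 (ENSMUSG00000009185), a chemokine for monocytes and T cells, was at 49.0 and 241 CPM, 4.92 times as high (4.39–5.53). Interferon targets Oas3, which senses double-stranded RNA (4.30, 2.61–7.49), the master regulator Irf7 (24.99 and 70.6 CPM, 2.82, 2.39–3.35), the nucleic acid sensor Zbp1 (2.97, 2.33–3.82) and the GTPase Gbp2 (2.91, 2.21–3.88) were all higher. So were the IgG receptor Fcgr4 (50.1 and 119 CPM, 2.38, 2.11–2.68), the IL-18 blocker Il18bp (2.38, 1.98–2.88) and the antigen-presenting chain H2-Eb1 (1522 and 2777 CPM, 1.82, 1.78–1.87). Apoc1, a lipoprotein component made under LXR, was 3.26 times as high (2.01–5.56). The resident-macrophage genes Lyve1, a hyaluronan receptor (5.14, 2.56–11.7, 5 and 19 cells), and Cd209f, a lectin (3.68, 1.86–8.07, 1 and 10 cells), rest on few cells.

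Lower in anti-miR-33pHLIP macrophages were single genes of inflammation and DNA replication and the elastase Mmp12. Ifnb1, the type I interferon itself, was at 30.8 and 14.1 CPM, 0.458 times as high (0.370–0.566), but 0.770 as a per-cell mean. Mmp12, which degrades elastin, was at 1006 and 668 CPM, 1.51-fold lower, and Gdf15, a stress cytokine, at 1379 and 932 CPM (0.676 times as high, 0.657–0.695). The alarmin Il1a (141 and 82.0 CPM, 0.584, 0.532–0.640), the urokinase receptor Plaur (0.585, 0.543–0.629) and the T cell costimulator Tnfsf9 (0.656, 0.632–0.682) were lower as well. Replication-linked histones Hist1h1b (0.530, 0.470–0.598), Hist1h1e (0.523) and Hist1h2ab (0.344), and the replication clamp factor Pclaf (0.470, 0.3802–0.580), were lower. Ifit1, an interferon target, ran against its group at 0.624 times as high (0.551–0.707). Cd207, the Langerhans cell lectin, was 2.89-fold lower, but 71.1% of its ScrpHLIP UMIs came from 1 cell, and as a per-cell mean it was 0.515 times as high.

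**Figure D3:**
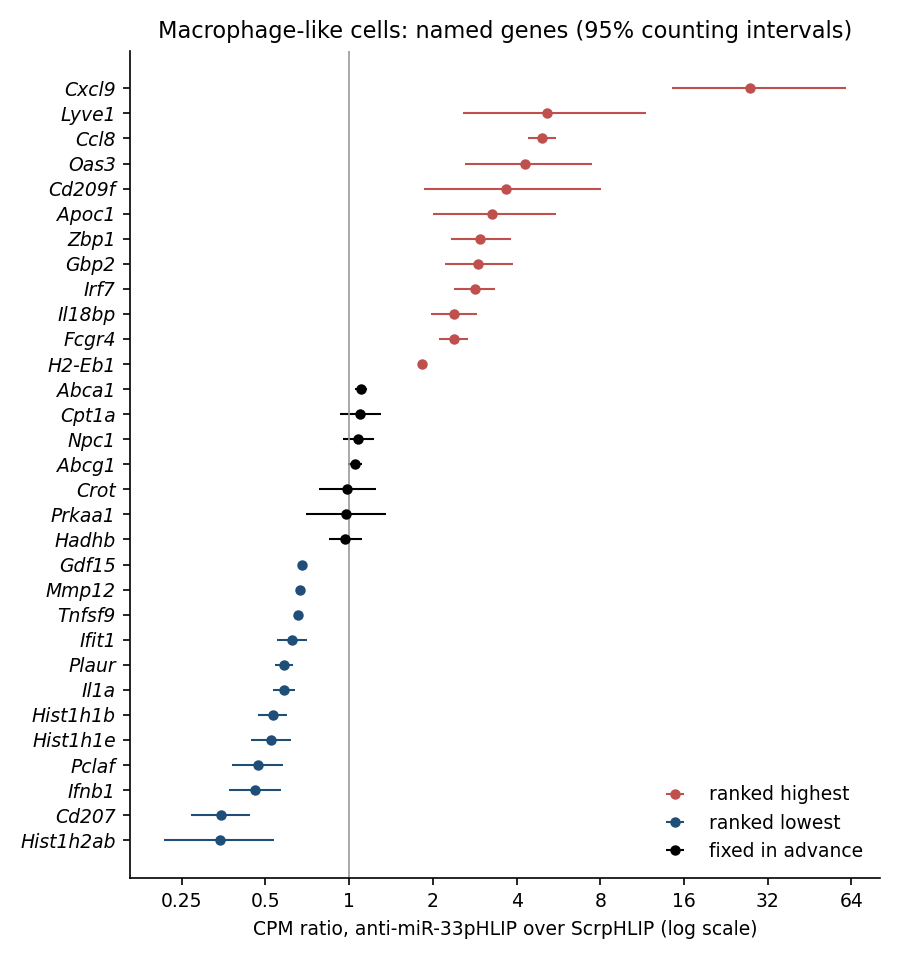
Ratio of anti-miR-33pHLIP to ScrpHLIP in macrophages for the named genes, with intervals for counting error. Cxcl9 was 27.7 times as high, Ccl8 4.92 times and Abca1 1.10 times.

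The genes through which miR-33 is known to act on cholesterol and fat were close to equal in macrophages. Abca1 (ENSMUSG00000015243) was at 367 and 405 CPM, and Abcg1, the exporter to HDL, was 1.05 times as high (0.991–1.12). The lysosomal cholesterol transporter Npc1 was 1.08 times as high (0.947–1.23). Of the fatty acid oxidation targets, Crot was 0.982 times as high (0.777–1.2462), Cpt1a 1.10 (0.926–1.30) and Hadhb 0.966 (0.843–1.11), and the energy sensor Prkaa1 was 0.970 (0.701–1.35). None of 25 published miR-33 targets passed the fold threshold for list members, and their median of 0.01 was at percentile 74.2 of random lists. Genes with a miR-33 site of 7 bases in the 3′ UTR (819 of 10919) had a median log2 ratio of 0.00, at percentile 72.2, and 160 of 419 control 7-base sequences had medians at least as high. The 222 genes with an 8-base site were at −0.01 (25.7) and the 3576 with a 6-base site at 0.00 (96.9). UTRs with a 7-base site are long, a median of 2637 bases against 1173 over all 10919 genes. In the other classes the target list lay between −0.01 in endothelial cells and 0.19 in fibroblast-like cells.

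Among lipid lists in macrophages, cholesterol biosynthesis was lower. Cholesterol efflux and LXR targets were near equal, with 17 of 20 genes within the threshold (0.06, percentile 97.6, but 88.2 with doublets kept and 88.7 at the automatic doublet threshold): Apoe, which carries cholesterol out of cells, was 1.22 times as high (1.22–1.23) and Abca2, an endosomal lipid transporter, 1.32, while the desaturase Scd1 was 0.752 times as high (0.606–0.933) and Abca7 0.634. Cholesterol biosynthesis genes were at −0.20 (0.36), 8 of 23 past the threshold, among them Acat2 (0.598, 0.398–0.897) and Mvk (0.764), with Fdft1, squalene synthase, higher at 1.27. Fatty acid oxidation genes were at −0.09 (2.83), oxidative phosphorylation at −0.02 (59.0), and glycolysis and hypoxia at −0.03 (43.8), none with a member past the threshold. Genes of lipid-associated macrophages were at −0.06 (19.8), and lower past the random range at −0.187 with doublets kept and −0.126 at resolution 0.5, but at 0.0549 (99.3) without interferon-state macrophages and 0.0142 inside cluster 20: the lipid receptor Trem2 was 1.00 times as high, the scavenger receptor Cd36 1.31, the tetraspanin Cd9 0.782 and the lipid chaperone Fabp4 0.787. Autophagy and lysosome genes were at −0.09 (5.22).

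Interferon and MHC class II genes were higher in macrophages and NF-kB genes lower. Interferon response genes had a median of 0.58 (percentile 100), 16 of 24 higher past the threshold, including the transcription factor Stat1 (1.66, 1.43–1.93), Oasl2 (2.14), the GTPase Ifi47 (2.76) and the interferon brake Usp18 (1.77), and 2 lower, among them Ifit3b (0.522). In this list Cxcl10, a T cell chemokine (1.01), and Isg15, a ubiquitin-like modifier (1.05), were near equal. MHC class II genes had a median of 0.42 (100), 8 of 13 higher: H2-Aa was at 1667 and 2778 CPM, the invariant chain Cd74 was 1.68 times as high, and the class II transactivator Ciita 1.61 (1.22–2.14). This difference lay in cluster 20 (0.76), with cluster 7 at 0.07. NF-kB inflammatory genes were lower (−0.13, 0.05), 8 of 24 past the threshold and none higher by as much, but within the random range at the automatic doublet threshold (−0.0803), at resolution 0.5 (−0.076) and with the few-UMI cluster added (−0.0526). Tnf was at 1446 and 1122 CPM, Cxcl2, a neutrophil chemokine, was 0.735 times as high, Ccl2, the monocyte chemokine, 0.794, and Il1b was at 1.16 (1.13–1.19) in the class but 0.836 and 1.05 inside clusters 7 and 20, so its class value reflects the mix of clusters. Dissociation stress genes were at −0.08 (5.51), none past the threshold.

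Resident macrophage genes were higher as a group. They had a median of 0.31 (percentile 99.99), 6 of 12 higher and none lower, such as the platelet factor Pf4 (1.48, 1.34–1.62), the folate receptor Folr2 (1.29) and the hemoglobin receptor Cd163 (1.90, 1.23–3.03). Alternative activation genes were at 0.20 (100), but at −0.0119 with cells as deposited, with 8 of 19 higher, such as Retnla, an IL-4 target (1.60, 1.33–1.93), and Il4ra (1.32), but 3 lower, among them the arginine enzyme Arg1 (0.679). Of the efferocytosis and complement genes (0.10, 99.9) 14 of 18 were within the threshold, and inside cluster 20 the list was at −0.0449: the dead-cell receptors Mertk (1.27, 1.11–1.46) and Axl (1.31) were higher, and the pro-resolving Anxa1 was lower (0.742). Chemotaxis and retention genes were at 0.03 (90.8), with the chemokine Ccl12 higher (1.61, 1.50–1.73) and the monocyte receptor Ccr2 lower (0.666). T cell regulation genes were at 0.43 (99.95, 9 genes), led by the IL-2 receptor Il2ra (2.27, 1.56–3.38), but at −0.0368 with per-cell means, and T cell markers in macrophages were higher too (1.30, 1.05–1.61). Endothelial activation genes were at 0.09 (95.5).

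Matrix genes in macrophages were higher in sum (0.23; percentile 100), 10 of 31 past the threshold, such as Col6a2 (1.74) and Postn (1.67), with Col8a1 lower (0.531), but the list was at −0.04 at the automatic doublet threshold, 0.0618 at resolution 0.5 and −0.30 inside cluster 20. Contractile smooth muscle genes were higher as well (0.32, 100), and smooth muscle markers in macrophages ran at 207 and 249 CPM (1.203, 1.13–1.28). Most of these genes are typical of stromal cells, so free RNA in the droplets can carry part of both lists. Against that, modulated smooth muscle genes were at −0.01 (69.4) and that class's markers were lower in macrophages (0.708). The matrix genes Thbs1 and Col14a1 were among the top 10 genes of macrophage subclusters. Whether the mix of macrophage states carries part of the matrix list was not tested. Macrophage matrix proteases were at −0.02 (57.0): cathepsin K, Ctsk (1.45, 1.33–1.59), and Mmp19 (1.34) were higher, while Mmp12 and the urokinase Plau (0.667) were lower. Protease inhibitors were at 0.04 (84.3).

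Cell cycle genes were lower in macrophages (−0.21; percentile 0), 10 of 24 past the threshold and none higher, such as thymidine kinase Tk1 (0.620), Tyms (0.646) and the mitotic factor Birc5 (0.636). The share of cycling macrophages was lower within counting error: after thinning to 2000 UMIs, 9.34% of ScrpHLIP macrophages (68 of 728, 7.33–11.7%) and 8.14% of anti-miR-33pHLIP macrophages (135 of 1659, 6.87–9.56%) had a UMI of Mki67 or Top2a, 0.871 times as high (0.646–1.18). The direction did not hold with doublets kept (1.35, 0.955–1.94) or with the few-UMI cluster added (1.13, 0.825–1.57). Thinning left out 39 and 141 macrophages. In modulated smooth muscle cells the same share was 0.251% and 0.344%, a rough gauge of what free RNA adds. It is no upper bound for macrophages, since these cells held more UMIs (median 13534 and 9404, against 8101 and 5495 in macrophages).

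Modulated smooth muscle cells had higher interferon genes and lower levels of several secreted proteins. The interferon target Ifit3 had 98 and 369 UMIs, 3.9997 times as high (3.19–5.05), and Ifit3b was 3.15 times as high (2.11–4.83). The protease inhibitor Spink5 was 2.49 times as high (2.27–2.73), the acute-phase protein Orm2 4.13 (2.43–7.37) and the calcium-binding Efcab1 2.55 (2.004–3.26). Jchain, which joins antibodies, had 10 UMIs in 10 cells and 69 in 26 cells (7.33, 3.76–15.96), and where this RNA came from was not tested. Red cell markers were at 19.3 and 104 CPM (5.38, 4.95–5.85) in this class. Chil1, a chitinase-like protein of cartilage and inflammation, was at 3695 and 1511 CPM, 2.45-fold lower (2.42–2.47), the transcription factor Foxd1 2.87-fold lower (2.45–3.38) and the chemoattractant Msmp 3.49-fold lower (0.407 times as high as a per-cell mean). Epyc, a cartilage proteoglycan (169 and 4 UMIs, 39.8-fold lower, 15.3–148), and Otos (117 and 2, 55.1-fold lower) came from 10 and 6 ScrpHLIP cells, and Xlr3b was 17.4-fold lower (6.52–65.6).

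The interferon list had a median of 0.82 in modulated smooth muscle cells, 16 of 23 genes higher past the threshold and 1, Irf1 (0.661), lower. Matrix genes were higher (0.24), 13 of 32, among them Col1a1 (1.41), Col6a3 (1.48) and Col5a2 (1.27). Markers of the modulated state were near equal (0.04), with the proteoglycan Acan higher (1.37) and the lubricant Prg4 (0.664), the bone factor Runx2 (0.752) and Ibsp (0.763) lower. Contractile genes were at 0.14, 7 of 20 higher. MHC class II genes had a median of 0.92, but Cd74 stood at 0.197% of its level in the highest class, within reach of free RNA, and macrophage markers here were at 134 and 158 CPM (1.18). Chemotaxis genes at 0.38 and resident macrophage genes at 0.62 carry the same limit.

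Contractile smooth muscle cells had higher interferon genes, and elastin was lower. Irf7 had 22 and 174 UMIs, 5.27 times as high (3.37–8.63), the GTPase Iigp1 was 4.15 times as high (3.17–5.50) and the acute-phase protein Saa3 3.98. That value came from cluster 11 (15.03), against 1.01 and 1.00 in clusters 14 and 15 and 0.442 in cluster 12, and as a per-cell mean Saa3 was 1.39, with 51.3% and 35.6% of its UMIs in 1 cell of each library. Grem1, a BMP blocker, had 8 UMIs in 7 cells and 204 in 27 cells (17.0, 8.46–39.9, per-cell mean 6.97), and the B cell chemokine Cxcl13 had 3 and 58 UMIs in 2 and 7 cells (12.9, 4.19–64.3). The chloride channel Ano2 was 4.85 times as high (2.19–12.7). Elastin, Eln, was at 7355 and 3380 CPM, 2.18-fold lower (2.14–2.21). Inside clusters it was 0.466 times as high in cluster 15, which held most of its UMIs, 0.721 in cluster 14, 0.769 in cluster 12 and 1.02 in cluster 11, so the mix of clusters adds to the class value. Also lower were Slit2, a guidance cue (3.14-fold), the hyaluronan-degrading Cemip (2.57-fold, but 0.870 times as high as a per-cell mean), the cyclin Ccnd1 (2.26-fold) and the collagen regulator Cthrc1 (2.08-fold).

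In lists, interferon genes had a median of 1.00 in these cells, 19 of 20 higher, and matrix genes −0.25, 12 of 32 lower, among them Col1a1 at 1.91-fold lower. The interferon list was past the random range in cluster 15 (1.73), while clusters 11 (0.22) and 14 (−0.28) lay inside the range of random lists. The matrix list was at 0.12 and 0.13 inside clusters 11 and 14 and at −0.16 inside cluster 15, so much of the class value reflects the mix of clusters, and with per-cell means the class value was 0.0979. Contractile genes were near equal (0.09) and matrix proteases at 0.18. MHC class II genes were at 0.99, with Cd74 2.42 times as high (2.22–2.64) at 1.57% of its highest class; macrophage markers were at 159 and 225 CPM (1.41, 1.29–1.55), so free RNA can carry part of it.

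**Figure D4:**
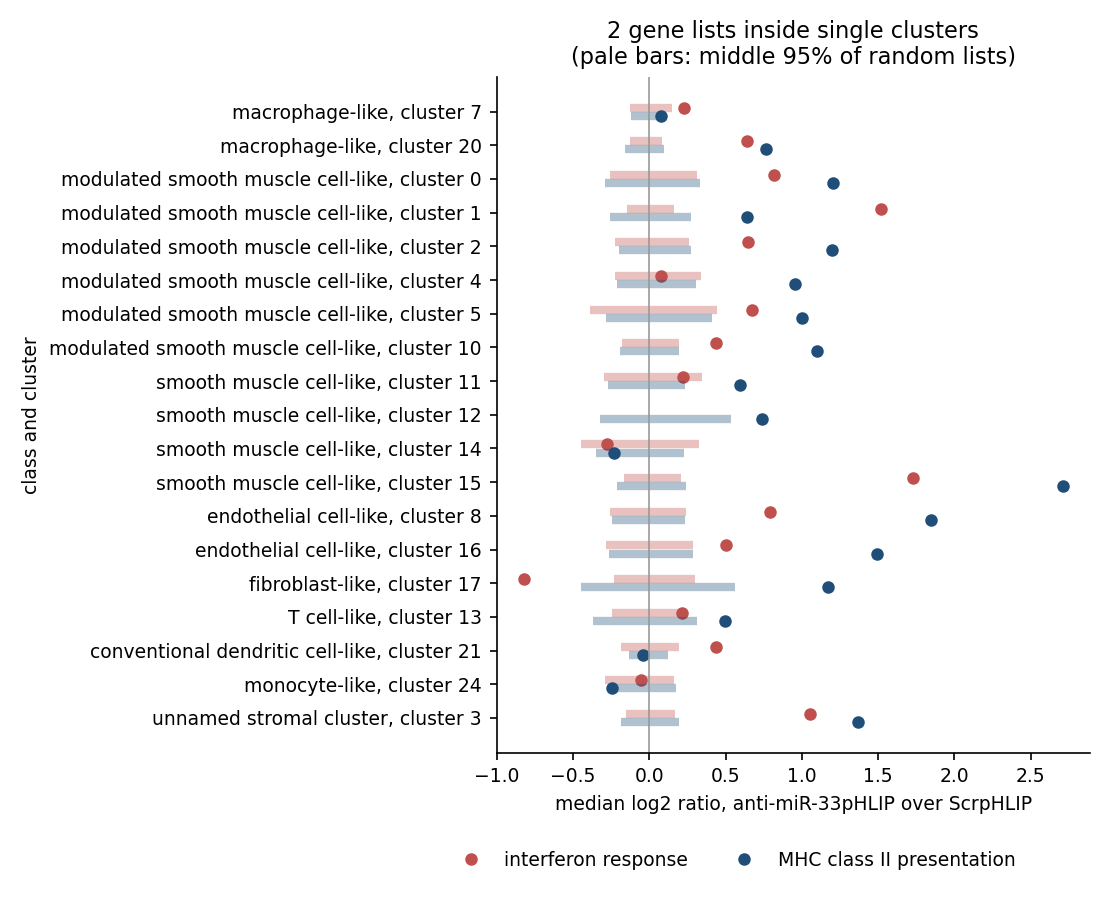
List medians inside single clusters. Interferon genes were at 1.73 in smooth muscle cluster 15 and −0.28 in cluster 14, and at 0.23 and 0.64 in macrophage clusters 7 and 20.

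Endothelial cells had higher interferon, MHC class II and cell cycle genes. Klf2, the flow-responsive regulator, was 0.515 times as high (0.489–0.542). Igfbp3, a growth factor carrier, had 68 UMIs in 8 cells and 532 in 23 cells, 9.58 times as high (7.43–12.5). The stretch gene Ankrd1, seen in 12 and 15 cells, was 8.19 times as high (4.82–14.8), or 17.5 (7.75–48.7) without cluster 22. The lymphatic genes Ccl21a (610 UMIs in 8 cells against 0; at least 166-fold lower) and Mmrn1 (114 in 9 cells against 0; at least 31.03-fold lower) came from few cells, and H19 (at least 13.9-fold lower) from 1. The prostaglandin enzyme Ptgds (468 and 7 UMIs, 54.6-fold lower), the collagenase Mmp13 (328 and 6, 44.6-fold lower) and the channel Kcnj15 (112 and 2, 45.7-fold lower, 12.4–382) came from cluster 22. The mitotic genes Top2a (2 UMIs, and 68 in 14 cells, 41.6, 11.1–351) and Prc1 (12.7, 5.12–40.9) were higher, and Chga (0, and 106 in 2 cells; at least 43.3-fold higher) and Gal (0, and 76 in 6 cells; at least 31.03-fold higher), both neuroendocrine peptides, came from a handful of cells.

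The endothelial interferon list had a median of 0.78, 17 of 20 higher, among them Gbp2 (2.85) and Stat1 (2.15), and was 0.62 without cluster 22. MHC class II genes were at 1.81, all 8 higher, with Cd74 5.23 times as high (4.68–5.85) and H2-Aa 4.01 (3.24–5.00). Macrophage markers in the class barely differed (237 and 251 CPM), but Cd74 was only 3.38% of its highest class. Cell cycle genes were at 1.95, with Top2a seen in only 14 anti-miR-33pHLIP cells, and cholesterol biosynthesis genes were at 0.45. Stress genes were at −0.62 and modulated smooth muscle genes at −0.40 with cluster 22, against 0.14 and 0.19 without it. Endothelial activation genes were near equal at 0.01, although the adhesion molecule Vcam1 was 0.744 times as high.

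Fibroblast-like cells ran opposite to the other stromal cells for interferon genes. The list was at −0.83, 12 of 19 lower: Ifit1 was 7.60-fold lower (58 UMIs in 10 cells, and 8 in 6), Ifit3 4.05-fold and Iigp1 3.64-fold. Matrix genes were at −0.25, with Cthrc1 33.0-fold lower (63 and 2 UMIs, 8.78–279), the calcification inhibitor Mgp 2.47-fold and Eln 2.23-fold lower (0.685 times as high as a per-cell mean). Higher were the Wnt modulators Sfrp4 (24 and 164 UMIs, 6.51, 4.23–10.5) and Sfrp2 (3.30, 2.92–3.74), the eosinophil chemokine Ccl11 (6.01), complement C2 (5.37), the ferritin receptor Scara5 (4.42) and Efemp1 (4.19). NF-kB genes were at 0.46, 8 of 15 higher and 4 lower, and chemotaxis genes at −0.58 over only 6 genes, or 0.19 with no count minimum. MHC class II genes were at 1.17, with Cd74 at 0.503% of its highest class, and macrophage markers were 1.69 times as high here. This class had 89 and 194 cells.

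T cells of the anti-miR-33pHLIP library had higher Tnfrsf4 and Ctla4 and lower Il17a and Gzmb. Tnfrsf4, the costimulator OX40, had 9 and 145 UMIs, 5.81 times as high (2.98–12.96), the checkpoint receptors Ctla4 (2.71, 1.75–4.39) and Lag3 (3.44, 1.85–7.10) were higher, and so were Tnfrsf18 (1.97), the regulatory factor Ikzf2 (1.61), the homing receptor Ccr7 (3.20, 1.96–5.54), the enkephalin gene Penk (2 and 88 UMIs, 15.9, 4.26–133), Rgs16 (6.25, 3.21–13.9), the thymic-selection gene Itm2a (3.36) and the interferon target Ifi27l2a (2.40, 1.92–3.03). Lower were Il17a (0.302, 0.181–0.500), the gamma-delta marker Cd163l1 (0.311, 0.203–0.475), the granzyme Gzmb (0.625, 0.530–0.739), Ifng (0.627, 0.485–0.815), the chemokine Xcl1 (0.434), the lymphotoxin Ltb (0.598), the cathepsin Ctsw (0.609), the costimulator Cd226 (0.506) and the glycosylation enzyme B4galt1 (0.532). The class pools a larger T cell cluster (144 and 584 cells) with a gamma-delta cluster (18 and 38 cells). Whether this mix of clusters carries the lower Il17a and Cd163l1 was not tested. T cell regulation genes had a median of 0.27, 11 of 22 higher and 6 lower, NF-kB genes 0.33 and interferon genes 0.19. Stromal matrix genes were at 0.61 in this class, macrophage markers 1.59 times as high and endothelial markers 0.415 times, and whether free RNA carries the matrix genes was not tested.

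Dendritic cells had higher interferon genes, and monocytes differed in single genes. In dendritic cells Cxcl10 had 79 and 244 UMIs, 3.17 times as high (2.45–4.14), with Ifit1 (2.94), Ifitm1 (2.18), the interferon regulator Irf1 (1.96, per-cell mean 1.2507), the prostaglandin enzyme Ptgs2 (2.11, per-cell mean 1.2458) and the vitamin B6 enzyme Pnpo (2.38) higher. Lower were the lectin Clec4n (0.291), Pira2 (0.367), the splicing factor Sf3b4 (0.316), Pxdc1 (0.398) and the histones Hist1h1b (0.220) and Hist1h2ae (0.354). For Hist1h1b, 55.9% of the ScrpHLIP UMIs came from 1 cell. The dendritic interferon list was at 0.50, MHC class II at −0.06, glycolysis and hypoxia at −0.32 and matrix proteases at −0.30. In monocytes the activin subunit Inhba (5.05), Saa3 (4.87, with 66.7% of anti-miR-33pHLIP UMIs in 1 cell, and 53.2% for Inhba), the decoy receptor Il1r2 (3.66), Il1a (3.12) and the protease inhibitor Slpi (2.05) were higher, and Cxcl9 had 0 and 51 UMIs in 6 cells (at least 10.0-fold higher). The lipid droplet gene Hilpda (0.469), the chemokine Ccl7 (0.480), Dtnbp1 (0.370), the polyamine enzyme Odc1 (0.520), cathepsin D, Ctsd (0.585), and galectin-3, Lgals3 (0.663), were lower. A single cell held 65.0% of the anti-miR-33pHLIP UMIs of Ccl7 and a single cell 58.8% of those of Cxcl9. The monocyte interferon list was at −0.06, MHC class II at −0.24 and lipid-associated genes at −0.35, and stromal matrix genes, which free RNA can carry, at 0.57.

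**Figure D5:**
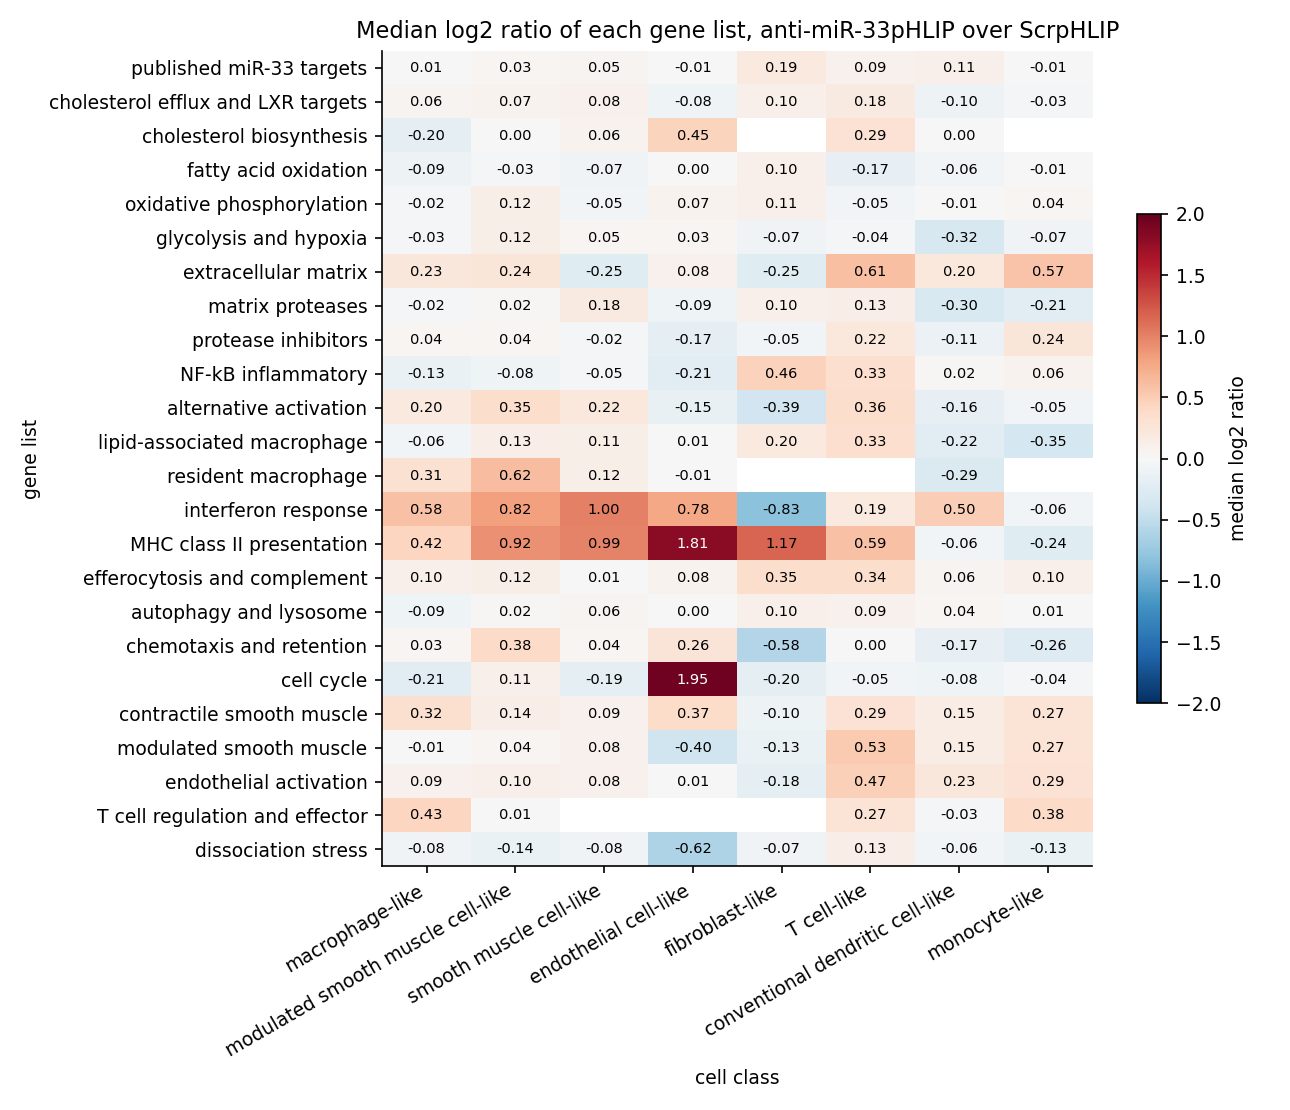
Median log2 ratio of each fixed list per class. Interferon genes were at 0.58 in macrophages, 0.82 in modulated smooth muscle cells, 1.00 in smooth muscle cells, 0.78 in endothelial cells and −0.83 in fibroblast-like cells.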

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

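The interferon list went in opposite directions between classes: the median log2 ratio was 0.82 in modulated smooth muscle cells, 1.00 in smooth muscle cells and 0.78 in endothelial cells, against −0.83 in fibroblast-like cells, and the difference between these classes was not tested. The fibroblast value rests on 89 and 194 cells.

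Immature thymocyte-like cells led by Dntt and Rag1, genes of antigen receptor assembly, were 0.836% of ScrpHLIP cells (51) and 3.06% of anti-miR-33pHLIP cells (309). They were kept out of the T cell class by markers added after seeing the data. The red cell genes Hbb-bs, at 487 and 1073 CPM over all barcodes, and Hba-a1, at 165 and 357 CPM, were higher in the anti-miR-33pHLIP library.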

How the results depend on the processing

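No paired analysis was possible because each group has 1 library with no shared animals named. All alternatives named in the methods were run. Values are ratios for shares and genes, and median log2 ratios for lists, and where a value moved the cause was not tested unless a sentence says so. Reversed is said only where the starting ratio had an interval clear of 1, or the starting list lay outside the random range, and the direction then changed. Other changes of direction count as moved or the same, by their size. Class shares were the same in 44 comparisons, moved in 14 and reversed in 3. The main list medians were the same in 101, moved in 44 and reversed in 6; for the other lists these counts were 1091, 175 and 15. State shares were the same in 22, moved in 5 and reversed in 1, and seed sites the same in all 8. Other macrophage genes were the same in 296 comparisons and moved in 32. Settings that keep single clusters, leave clusters out or add clusters with few UMIs were chosen after seeing the data.

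With the strict cell filter the smooth muscle share ratio was 1.30, fibroblast 0.968 (reversed) and T cell 1.46, and LXR targets in macrophages were at 0.0528. Removing doublets at Scrublet's automatic threshold gave a macrophage share ratio of 1.15, LXR 0.0351, matrix −0.04 (reversed), NF-kB −0.0803 and lipid-associated genes −0.12. It marked only 2 barcodes in ScrpHLIP against 323 in anti-miR-33pHLIP, so this setting treats the libraries unequally. Keeping doublets gave Abca1 1.03 (0.986–1.08), LXR 0.0257, matrix 0.76, lipid-associated −0.19, MHC class II 0.30 and a cycling share ratio of 1.35 (the other way from 0.871). Cells as deposited gave LXR 0.0501, alternative activation −0.0119 (reversed) and an interferon state ratio of 3.90.

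Leiden resolution 0.5 gave a macrophage share ratio of 1.16, matrix 0.0618, NF-kB −0.076 and lipid-associated genes −0.13, and resolution 2 a smooth muscle share ratio of 0.875 (the other way from 1.06) and LXR 0.0599. Clustering each library alone gave share ratios of 1.69 for macrophages, 0.888 for modulated smooth muscle cells, 0.723 for endothelial cells, 1.80 for T cells, 1.645 for dendritic cells (the other way from 0.944) and 0.454 for monocytes (reversed), and in macrophages LXR 0.055, matrix 0.35 and MHC class II 0.55. Among leukocytes only, the ratios were 0.965 for macrophages (reversed), 1.00 for monocytes, 0.642 for dendritic cells and 1.58 for T cells. Within macrophages, resolution 2 gave an interferon state ratio of 2.82 and resolution 0.5 an inflammatory state ratio of 0.905. Counting in the unnamed interferon-gene cluster, also chosen after seeing the data, gave an interferon state ratio of 2.69.

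Adding the macrophage cluster with few UMIs gave a macrophage share ratio of 1.15, matrix 0.037, NF-kB −0.0526, lipid-associated genes −0.12, inflammatory state 1.12 (reversed) and foamy state 1.22 (the other way from 0.980). Inside macrophage cluster 20, LXR was 0.21, matrix −0.30 (reversed), NF-kB −0.24, lipid-associated 0.0142 (the other way from −0.06), MHC class II 0.76 and efferocytosis −0.0449 (reversed). Inside cluster 7, matrix was 0.60, NF-kB −0.25, interferon 0.23 and MHC class II 0.0747. Without interferon-state macrophages, NF-kB was −0.24, lipid-associated 0.0549 (also the other way), interferon 0.005 and MHC class II 0.32.

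The mean of per-cell CPM gave Abca1 1.05, Grem1 6.97 in smooth muscle cells and Cxcl10 2.44 in dendritic cells. In macrophages it gave LXR 0.0471, interferon 0.69, MHC class II 0.55 and T cell regulation −0.0368 (reversed). In smooth muscle cells it gave matrix 0.10 (reversed), interferon 0.85 and contractile −0.0469 (reversed). The same setting gave interferon 0.53, MHC class II 1.59 and protease inhibitors 0.015 (reversed) in endothelial cells, and in monocytes modulated smooth muscle −0.0484 and endothelial activation −0.0537 (both reversed). A count minimum of 100 gave LXR 0.0582 and MHC class II 0.60 in macrophages, interferon 0.83 in smooth muscle cells and MHC class II 2.15 in endothelial cells. With no minimum, fibroblast chemotaxis was 0.19 (reversed).

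Inside smooth muscle cluster 11, matrix was 0.12 (reversed) and interferon 0.22. Inside cluster 14, matrix was 0.13, interferon −0.28, MHC class II −0.23 and contractile −0.10, all reversed. Inside cluster 15, matrix was −0.16, interferon 1.73 and stress 0.27 (reversed). Without endothelial cluster 22, protease inhibitors were 0.0401, NF-kB 0.10, modulated smooth muscle 0.19 and stress 0.14, all reversed, which places those class values in that cluster.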

Other observations

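The cartilage-like clusters were not all a smaller part of the anti-miR-33pHLIP library. The descriptions below as hypertrophic, early cartilage or acute-phase are not among the fixed marker types, and whether they hold was not tested. Cluster 0, which resembles hypertrophic chondrocytes, was 5.88% of ScrpHLIP cells (359) and 2.61% of anti-miR-33pHLIP cells (263), 0.443 times as high (0.376–0.521). Cluster 5, with the mineralization genes Ibsp and Alpl, was 3.26% (199) and 1.96% (198), 0.602 times as high (0.492–0.736). The acute-phase clusters 1 and 4 were 7.39% and 4.96% (0.672), and 7.21% and 4.67% (0.647). By contrast the collagen-rich cluster 2 was 7.14% and 7.23% (1.01), and cluster 10, which resembles early cartilage, 9.96% and 11.05% (1.11, 1.00–1.23). Inside every one of these clusters matrix genes had a positive median, from 0.09 in cluster 10 to 0.33 in cluster 0, and interferon genes ranged from 0.08 in cluster 4 to 1.52 in cluster 1.

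The small gamma-delta T cell cluster, led by Trdc, was 0.295% (18) and 0.376% (38) of cells, 1.28 times as high (0.711–2.38), while the larger T cell cluster was 2.36% (144) and 5.79% (584), 2.45 times as high (2.04–2.96).

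Of the tests below, only the thinning test and the test of the cartilage-led subcluster were planned in advance. The free RNA tests, the interferon-state test, the thymic tissue test and the strict filter test for T cells were chosen only after the result was seen. The ranges after the medians 42.5%, 0.78 and 1.59% come from 2000 draws with replacement of the list members. They show the spread between genes, which are not replicates, and not counting error.

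As class values, interferon genes were higher in macrophages, smooth muscle and endothelial cells. Inside contractile smooth muscle clusters 11 (0.22) and 14 (−0.28) the list lay within the random range. Free RNA from macrophages would carry the interferon genes at the level of macrophage markers. In contractile smooth muscle cells they stood at 42.5% of the macrophage level (29.5–66.0%) against 0.947% for macrophage markers, and in endothelial cells at 66.1% against 1.13%. That rules out free RNA from macrophages in these classes, while modulated smooth muscle cells were not tested. With the macrophages of both libraries thinned to the same UMIs per cell, the interferon list median was 0.78 (0.48–0.89). Random thinning keeps each cell's expected proportions, and the thinned cells kept the classes they already had. The thinning test therefore cannot decide whether fewer UMIs per cell play a part, for example through doublet scores or clustering. Without the interferon-state macrophages the list median was 0.005, but those cells were named by these genes, so that test decides nothing, and inside cluster 7 the median was 0.23. Whether the construct, the animals or the preparation lies behind the difference stays open with 1 library per group, although a response to interferon could be part of it.

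The larger T cell share may include lymphoid tissue taken along with the aorta. Immature thymocyte-like cells were more frequent in the same library. Naive T cell markers such as Ccr7 and Lef1 were higher within T cells, as that explanation requires, with a median of 0.71 over 5 genes. Their log2 ratios ran from 0.08 in the lowest gene to 1.64 in the highest, which is a range and not an interval. Shallow barcodes called as T cells do not account for all of it, since with the strict filter the share was still 1.46 times as high (1.21–1.77). A larger T cell influx remains possible beside it, and these data cannot separate the 2.

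Higher matrix and contractile genes in macrophages may come from free RNA of stromal cells, which stays open. Both lists together stood at 1.59% of their highest class (1.40–2.30%), a background level, and smooth muscle markers in macrophages were higher (1.203), but markers of modulated smooth muscle cells, the largest stromal class, were lower (881 and 624 CPM, 0.708, 0.684–0.733). Without the macrophage subcluster led by cartilage genes the matrix list median was 0.48, so the higher value does not rest on those cells. That group was the larger part of ScrpHLIP macrophages, 2.22% (17 cells) against 1.5% (27). Leaving it out could therefore hardly have lowered the median, and the test says little about doublets. Doublets elsewhere stay open, with medians of 0.76 when doublets were kept and −0.04 at Scrublet's automatic threshold. That threshold marked 2 barcodes in ScrpHLIP and 323 in anti-miR-33pHLIP, so it treats the libraries unequally and cannot decide the question. The main setting also removed unequal shares, 6.22% and 10.7% of barcodes by score. Why the median moved was not tested.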
